A study of Arabidopsis thaliana with 104 samples.

How the data were processed

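RNA was measured in libraries of whole Arabidopsis thaliana seedlings: Col-0, phr1 and phr1 phl1, each at 50 µM or 625 µM Pi, without bacteria or with SynCom. Germination was on 1 mM Pi with 0.5% sucrose for 7 days, and treatment lasted 12 days, per the labels' protocols. The labels name 5 independent experiments, each with 2 libraries per group, and phr1 phl1 was present in 3 of them. The libraries were made from poly(A) RNA without strand information, per the labels. The deposited values are raw read counts per gene. Per the submitters' processing notes the tools were CASAVA 1.8, cutadapt 1.3, TopHat2 2.1.1 and HTSeq 0.6.1p1 with build TAIR10, and their roles and settings are not given in the sources used here. Reads shared by near-identical genes, or by genes that overlap on either strand, can be assigned to neither or to the wrong gene under such counting.

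The count table held 27206 loci, of which 1788 had no count in any library, and 0 columns were left unused. Names and neighbours came from a gene table of the assembly TAIR10.1, which held 26719 of the loci, and its gene positions served only to find genes that overlap each other. No coordinates are given, because the build differs by name. Total counts ran from 955174 to 9550846 per library, and genes with few counts are measured with the least precision. Library pairs of the same group were compared by chi-square over genes. The lowest value per degree of freedom among 420 pairs was 1.916 against a median of 5.099 within experiments, so no library was counted as a duplicate. Deviations from group means correlated at a median of 0.506 between libraries of the same experiment and -0.29 between experiments. Within an experiment the median was -0.0472 for libraries with the same number and -0.0562 for others, so experiment paired the libraries and the number added nothing.

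All statistics were computed in R 4.3.3. Counts were filtered by edgeR's filterByExpr over the 12 groups, which left 18926 genes, scaled by TMM and fitted by edgeR 4.0.16 with 1 coefficient per group and experiment as a covariate. Each of 25 contrasts was tested by the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05, and every adjusted p of a gene comes from this test unless another tool is named. The contrasts were low against high Pi, SynCom against no bacteria, each mutant against Col-0 in each condition, the Pi by SynCom interaction in Col-0 and the genotype by Pi interactions. Folds are log2 fold changes. Their standard errors were taken as the size of the fold over the square root of the F statistic. Both are least certain where several libraries of the lower group held 0 counts. CPM values are means ± SD of counts scaled to the library total over the genes left by the filter, adjusted by the TMM factor. The same model without other experiments gave the values of single experiments. The fit took the 2 libraries of a group in 1 experiment as independent, though they share that experiment. Where an effect differed between experiments, the standard errors and adjusted p are therefore too small. Contrasts of phr1 phl1 with Col-0 set experiments C, D and E against A to E. An effect that differs between experiments can therefore pass into them. Contrasts that share libraries are not independent of each other, and overlaps between them were not computed.

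Gene lists, contrasts, the tests of the contrasts, the rule for named genes and all alternatives except the fit without 4 libraries were fixed before the data were examined. The 17 lists hold 309 genes of Pi transport and signalling, phosphatases and Pi scavenging, membrane lipid remodelling, anthocyanin synthesis, salicylic acid and systemic resistance, jasmonate, pattern-triggered immunity, aliphatic glucosinolates, sulphur deficiency, iron deficiency, ferritins, nitrate, senescence, the mitotic cell cycle, photosynthesis as a shoot marker, and root hair and endodermis with stele as root markers. Each list was tested by camera in limma 3.58.1 with a preset correlation of 0.01 and with an estimated correlation, adjusted over 425 pairs of list and contrast. The preset correlation gave 183 calls and the estimated one 30, and all 30 were among the 183. Counts of list members in the results cover only the members among the genes tested. The named genes were PHR1 and PHL1, up to 4 members of each list with the smallest adjusted p, and the 5 highest and 5 lowest folds at adjusted p under 0.05. Genes named by fold also needed a mean of at least 1 CPM in the higher group and 1 sign in every experiment alone.

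Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter, a filter of 5 CPM in 6 libraries, no experiment term, a block of experiment and number, experiments C, D and E alone, each experiment left out and a fit of the compared groups alone. A fit without 4 libraries was chosen after seeing the data: they had fewer than 1000000 counts or a residual SD over 0.65. For each contrast 40 splits of the compared libraries were refitted: the real one, and others with single libraries shuffled within experiments. The rule for counting mirrored splits was completed after a first set of split counts had been seen. The tests were tried on simulated counts with 200 changed genes, picked among those above 1 CPM. Libraries were drawn independently, with 1 spread per gene in all groups and effects alike in every experiment. The real data differ in this, so neither the shares nor the false calls below carry over to them. For low against high Pi in Col-0 with SynCom, edgeR called 88% of genes changed by 1 and 99% of genes changed by 2 on the log2 scale, over 18707 genes, and 17 unchanged genes. The shares for phr1 phl1 against Col-0 at low Pi with SynCom were 79% and 94% over 18696 genes, with 14 unchanged genes called. For the Pi by SynCom interaction they were 66% and 97% over 18686 genes, with 17 unchanged genes called, and for the phr1 phl1 by Pi interaction without bacteria 64% and 92% over 18705 genes, with 16. For low against high Pi in Col-0 with SynCom, fitted on the 20 libraries compared, DESeq2 called 92% and 100% and limma-voom 90.1% and 100%. DESeq2 and limma-voom called 30 and 27 unchanged genes there.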

Results

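The series measured polyadenylated RNA of whole Arabidopsis thaliana seedlings that were grown at low or high inorganic phosphate (Pi), with or without a synthetic community of bacteria (SynCom). Col-0, the standard laboratory accession, was compared with mutants in PHR1 (phr1) and in both PHR1 and PHL1 (phr1 phl1). PHR1 and PHL1 are transcription factors that switch on Pi starvation genes. Seedlings grew for 7 days on 1 mM Pi and 12 more days on plates with 50 µM (low) or 625 µM (high) Pi. The libraries came from 5 independent experiments, A to E, and fell into 12 groups. Each Col-0 and phr1 group held 10 libraries, 2 from each experiment, and each phr1 phl1 group held 6, from experiments C, D and E. Total counts ran from 955174 to 9550846 per library, with a median of 4335782. Groups at low Pi with SynCom had medians of 5248210 counts in Col-0, 4781729 in phr1 and 2695984 in phr1 phl1. Experiment was the largest source of variation: the first principal component held 37.4% of the variance, and 93.4% of that component was tied to experiment. The second held 12.8%, of which 27.6% was tied to Pi and 25.5% to bacteria.

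PHR1 mRNA was lower in both mutant genotypes. Its level was 68.0 ± 9.92 CPM in Col-0 (SD, n = 40), 37.0 ± 9.48 CPM in phr1 (SD, n = 40) and 38.6 ± 9.24 CPM in phr1 phl1 (SD, n = 24). PHL1 mRNA was 13.5 ± 3.65 CPM in Col-0, 13.8 ± 3.87 CPM in phr1 and 135 ± 182 CPM in phr1 phl1, where single libraries ran from 42.0 to 972 CPM. The double mutant held more PHL1 mRNA than Col-0 in each of the 4 conditions, by 2.35 to 4.04 on the log2 scale. The highest of these, at high Pi without bacteria, was 3.06 without 4 libraries that stood apart, among them the one with 972 CPM, a fit chosen after seeing the data. PHR1 fell by 0.72 to 1.05 in phr1 and by 0.93 to 1.0 in phr1 phl1 over the same conditions. The mutant alleles are not given in the labels, so mRNA read outside a disrupted part does not test whether a functional product was made. PHR1 also overlaps AT4G28600, and the counts carry no strand, so part of its signal is uncertain. The same holds for CDKB2;2, GDPD1, PLDZETA2, FER2, PAP10, PAP17, PAP24, CASP1, CA1, SKOR, CHS, IMA3, FRK1, CYP81D11, BHLH038, OCT1 and FLC, each of which overlaps another annotated gene.

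Low Pi alone, without bacteria, moved few genes in Col-0. The non-coding RNA AT4, induced by Pi starvation, rose by 2.51 ± 0.42 (log2 fold change ± SE, n = 10 libraries per group from 5 experiments). The Pi transporter gene PHT1;2 rose by 3.47 ± 0.76, from a level at which 5 of 10 high Pi libraries held 0 counts. IPS1, a related non-coding RNA, reached 3.01 ± 8.0 CPM (SD) at low Pi against 0.0689 ± 0.177 CPM at high Pi, where 8 of 10 libraries held 0 counts, so no fold is given. AT4 reached 35.3 ± 40.4 against 5.06 ± 1.35 CPM. The small heat shock genes AT1G53540 and HSP17.6II, chosen after their values were seen, fell by 4.19 ± 0.64 and 2.77 ± 0.56. These 5 genes were all that passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, with adjusted p from 2.34e-05 to 0.0475. An unadjusted p under 0.05 was found for 372 genes. That is a share under 0.05 of the 18926 genes tested, fewer than p-values spread evenly would give. The test may thus be too cautious here, and the few calls do not show that other genes stayed unchanged. IPS1, AT4, PHT1;2 and AT1G53540 kept their sign in 4 of the 5 experiments and HSP17.6II in 3. Without experiment B, IPS1, AT4 and PHT1;2 lost their calls (adjusted p = 1, 0.157 and 1). IPS1 did so also without C or D (adjusted p = 0.0815 and 0.0693). PHT1;2 missed the threshold without A, C or D, in DESeq2 and with a block of experiment and number (adjusted p = 0.137, 0.086, 0.0724, 0.618 and 0.0939). Without experiment A, AT1G53540 lost its call (adjusted p = 1) and HSP17.6II turned to 0.55. HSP17.6II was not called in DESeq2 or with the block (adjusted p = 1 and 0.075), and limma-voom called AT4 alone of the 5. In experiments C, D and E alone edgeR called 0 genes, with 274 at an unadjusted p under 0.05. There AT4, IPS1, PHT1;2 and HSP17.6II each had an adjusted p of 1, AT1G53540 fell below the filter on low counts, and no other tool was run. A fit of the compared groups alone called 1 gene, AT4 (adjusted p = 0.019). Of 40 splits of those libraries, the real one included, 4 called as many, the highest other 45. Of 23 measured members of the Pi transport and signalling list 3 rose (5 adjusted over the list alone), and the list had a median of 0.52 (camera adjusted p = 2.77e-07, and adjusted p = 0.0861 with an estimated correlation). Of 19 phosphatase and Pi scavenging genes 0 passed over all genes tested in edgeR, DESeq2 or limma-voom, 6 had an unadjusted p under 0.05 in edgeR, and 4 rose when adjusted over the list alone. In the mutants edgeR called 0 genes in phr1 and 0 in phr1 phl1, with 1028 and 1099 genes at an unadjusted p under 0.05. DESeq2 called 76 and 4 genes there, and limma-voom called 0 and 0.

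Low Pi with SynCom changed many genes in Col-0, and most genes of the 3 lists of Pi starvation genes rose. IPS1 went from 0.272 ± 0.364 CPM at high Pi to 535 ± 446 CPM at low Pi, with an adjusted p of 3.73e-32. AT4 went from 10.2 ± 3.47 to 2228 ± 1460 CPM. SPX1, which encodes a Pi-dependent inhibitor of PHR1, rose by 5.75 ± 0.28, PHT1;9 by 5.04 ± 0.31 and PHT1;2 by 7.49 ± 0.39. PHT1;2 shares near-identical sequence with PHT1;1 and PHT1;3, so its share of the reads is uncertain. Of the 23 measured genes of Pi transport and signalling 18 rose and 4 fell (18 higher and 4 lower adjusted over the list alone), with a median of 3.97 (camera adjusted p = 5.93e-19). The members that fell were SPX4, PHO2, NLA and PHT5;3. PHO2 and NLA encode ubiquitination enzymes that limit Pi transporters, SPX4 restrains PHR1, and PHT5;3 belongs to a family of vacuolar Pi transporters. Among phosphatase and Pi scavenging genes 17 of 19 rose (17 adjusted over the list alone, median 4.19, camera adjusted p = 5.32e-24). They included PEPC1 at 8.93 ± 0.52, PPsPase1 at 9.22 ± 0.57 and the purple acid phosphatase genes PAP12 at 2.34 ± 0.13 and PAP24 at 6.29 ± 0.41. Of 17 genes that replace phospholipids by other membrane lipids 14 rose and 2 fell (14 higher and 2 lower adjusted over the list alone, median 2.56, camera adjusted p = 2.81e-18). The sulfolipid synthase gene SQD2 rose by 3.64 ± 0.21, the phospholipase gene PLDZETA2 by 5.21 ± 0.31 and the phosphodiesterase genes GDPD1 and GDPD3 by 3.43 ± 0.2 and 6.57 ± 0.41, while PLDZETA1 and GDPD2 fell. The largest adjusted p among the genes given with a value in these lists was 5.36e-27. At high Pi with SynCom IPS1 and PAP24 held 0 counts in 5 of 10 libraries and PHT1;9, PHT1;2 and GDPD3 in 4 of 10, so their levels there rest on few counts. Each of the genes had the same sign in all 5 experiments.

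**Figure D1:**
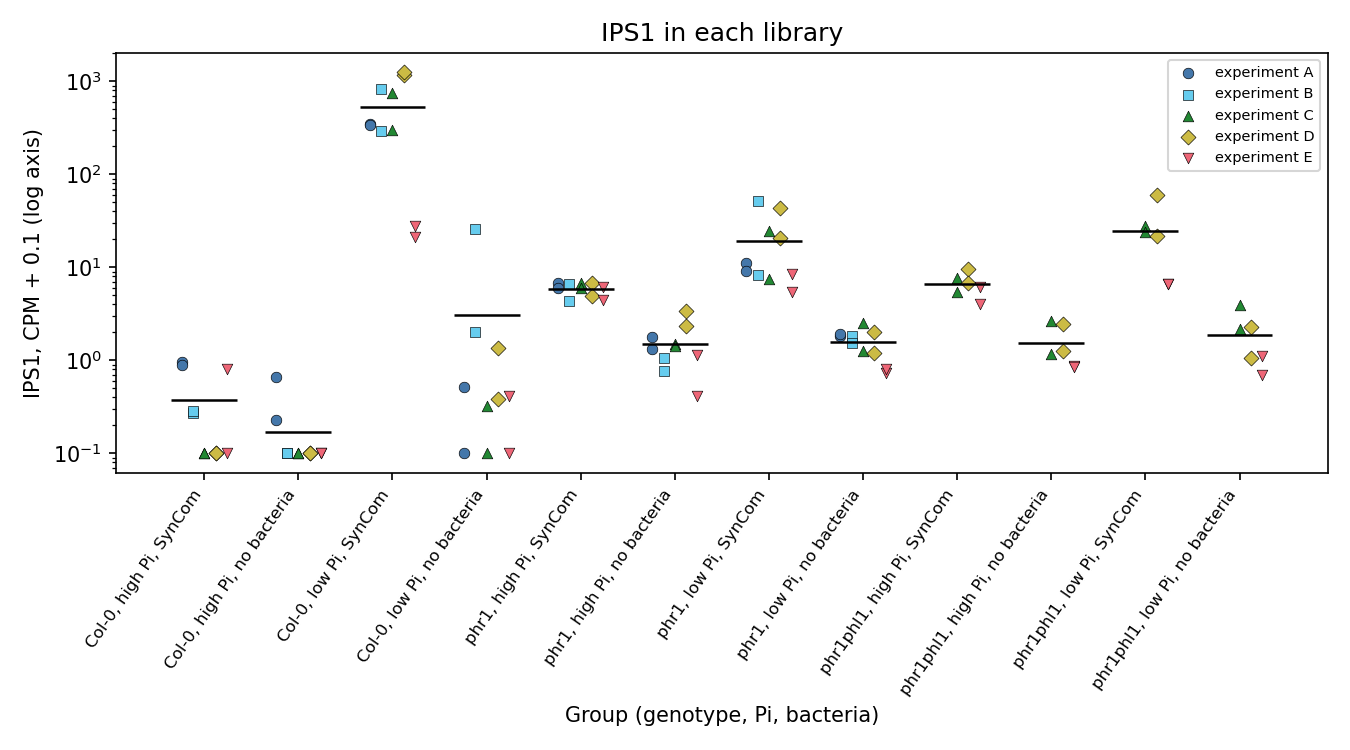
IPS1 in CPM in each library by group, on a log axis after adding 0.1, with marker and colour giving the experiment and black bars the group means. The group mean was 535 ± 446 CPM (SD) in Col-0 at low Pi with SynCom and 19.0 ± 16.3 CPM in phr1 in that condition.

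Many genes of salicylic acid signalling and of glucosinolate and anthocyanin synthesis also rose in Col-0 at low Pi with SynCom. PR1, a marker of salicylic acid signalling, went from 1.87 ± 2.97 to 75.3 ± 113 CPM, and PR2 and WRKY54 rose by 3.15 ± 0.59 and 1.71 ± 0.3. WRKY62 went from 0.0955 ± 0.132 CPM, with 0 counts in 6 of 10 libraries, to 3.94 ± 4.24 CPM (adjusted p = 2.24e-10). Of 23 salicylic acid and systemic resistance genes 13 rose (13 adjusted over the list alone, median 1.06, camera adjusted p = 0.00688, and adjusted p = 0.734 with an estimated correlation). Aliphatic glucosinolate synthesis genes rose in 17 of 19 cases (17 adjusted over the list alone, median 1.31, camera adjusted p = 3.51e-05, and adjusted p = 0.59 with an estimated correlation), among them the regulator MYB28 at 1.31 ± 0.2 and the sulfotransferase gene SOT17 at 2.3 ± 0.24. Anthocyanin synthesis genes rose in 8 of 9 cases (9 adjusted over the list alone, median 1.17, camera adjusted p = 0.0278, and adjusted p = 0.552 with an estimated correlation), with chalcone synthase CHS at 1.21 ± 0.16 and the regulator MYB75 at 3.0 ± 0.43. MYB75 is close in sequence to MYB90, so its value is uncertain. The anthocyanin list members MYB90, F3H, UF3GT, 5MAT and TT8 were not among the genes tested. Sulphur deficiency genes rose in 6 of 11 cases (6 adjusted over the list alone, median 0.54, camera adjusted p = 0.00278, and adjusted p = 0.274 with an estimated correlation), led by LSU2 at 3.33 ± 0.35. Mitotic cell cycle genes rose in 11 of 14 cases (11 adjusted over the list alone, median 0.76, camera adjusted p = 0.0109, and adjusted p = 0.698 with an estimated correlation), with CDKB2;2 at 1.2 ± 0.18. All 20 photosynthesis genes that passed, of 22, fell (20 adjusted over the list alone, median -0.82, camera adjusted p = 6.18e-09, and adjusted p = 0.556 with an estimated correlation), and the carbonic anhydrase gene CA1 fell by 1.17 ± 0.21. Root hair genes rose in 12 of 14 cases (12 adjusted over the list alone, median 1.08, camera adjusted p = 0.00922, and adjusted p = 0.633 with an estimated correlation), with the root hair regulators RHD6 at 2.19 ± 0.3 and RSL2 at 1.75 ± 0.26. Endodermis and stele genes rose in 6 of 11 cases and fell in 1 (6 higher and 1 lower adjusted over the list alone, median 0.49). Shoot and root tissue markers thus moved in the same comparison as the other groups in these whole seedlings. The calls of the 3 Pi starvation lists held with an estimated correlation.

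The remaining lists gave no camera call in Col-0 at low Pi with SynCom. Pattern-triggered immunity genes rose in 9 of 31 cases and fell in 2 (8 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.42), and jasmonate genes rose in 5 of 26 (2 adjusted over the list alone, camera adjusted p = 0.904). Of 20 nitrate uptake and response genes 7 rose and 3 fell (7 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.884). Nitrate reductase NIA1 and nitrite reductase NIR1 fell by 1.88 ± 0.26 and 0.84 ± 0.14, while the transcriptional repressor HHO1 rose by 2.6 ± 0.33. Iron deficiency genes rose in 1 and fell in 5 of 21 cases (1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.397). Ferritin genes rose in 1 of 3 cases (1 adjusted over the list alone, camera adjusted p = 0.644), with FER2 at 1.26 ± 0.3. Senescence genes rose in 1 and fell in 4 of 8 cases (1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.107), and the endodermis and stele list had a camera adjusted p of 0.321. Outside the lists, the potassium channel gene SKOR fell by 2.81 ± 0.28 and the small peptide gene RTFL21 by 3.19 ± 0.31.

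In Col-0 with SynCom, 9461 of 18926 genes passed at low against high Pi, 5214 higher and 4247 lower, of which 1697 rose and 366 fell by more than 2-fold. The low Pi group held 1 of the 4 libraries that stood apart, replicate 2 of experiment D (1615792 counts, residual SD 0.893). Fitted alone, experiments A, B, C, D and E called 6434, 5210, 3520, 5721 and 43 genes, and 68.5% of the genes called over all 5 had the same sign in E alone. The median of the Pi transport and signalling list was 4.15, 4.5, 4.3, 5.22 and 2.0 in the same order. The value was lowest in experiment E. In single experiments the median of the photosynthesis list ran from -2.46 to 0.02 and the glucosinolate list from -0.21 to 2.48.

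**Figure D2:**
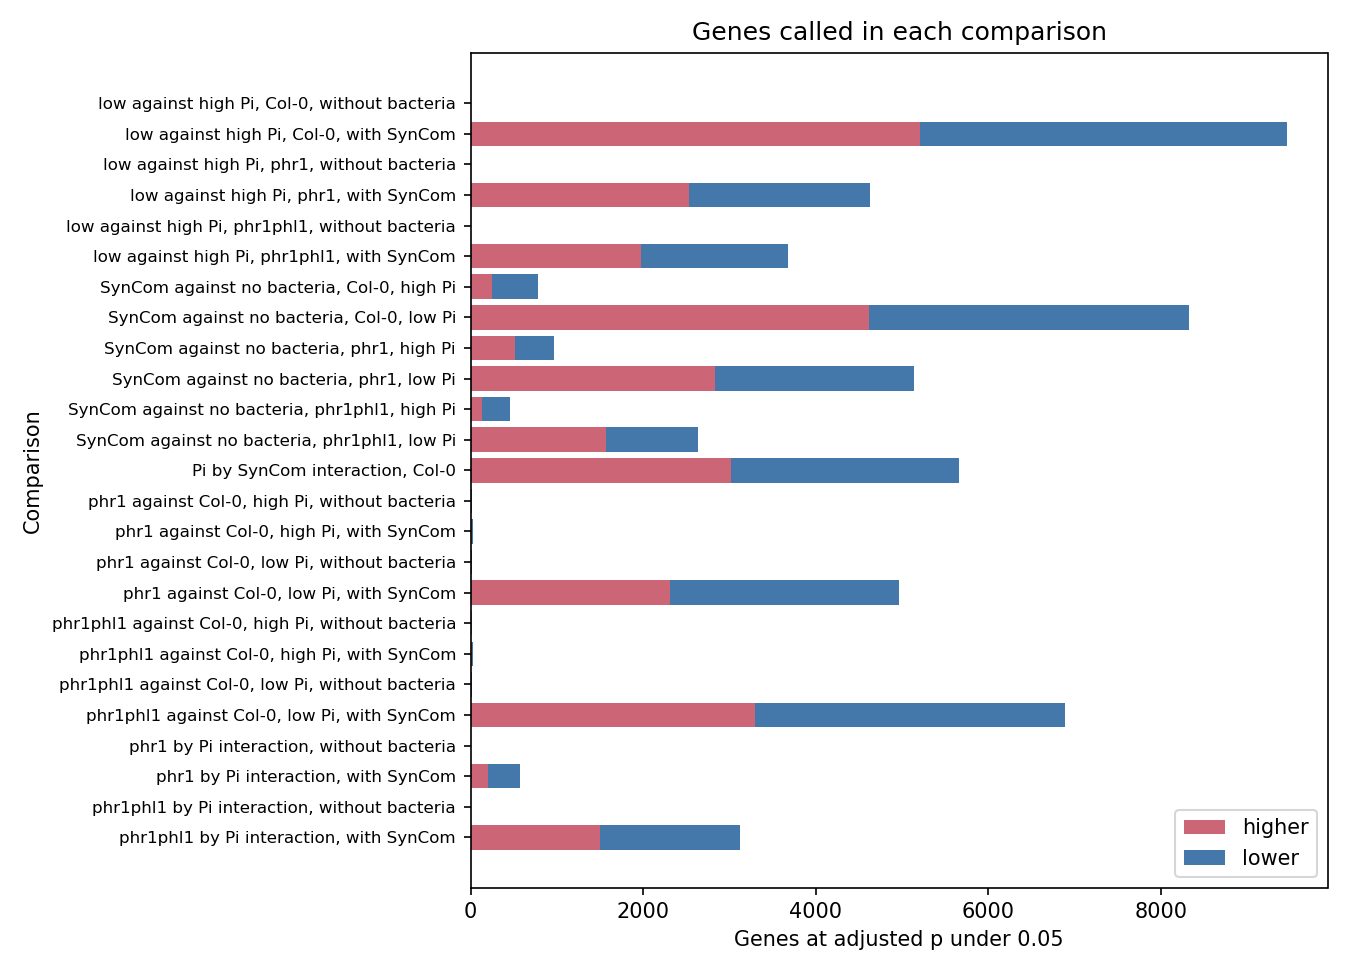
Genes at adjusted p under 0.05 in each of the 25 comparisons (edgeR), with higher genes in red and lower genes in blue. Low Pi in Col-0 gave 9461 genes with SynCom and 5 without bacteria.

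SynCom at high Pi changed fewer genes than low Pi with SynCom did. In Col-0 the glutathione transferase genes GSTU24 and GSTU25 fell by 3.01 ± 0.26 and 3.06 ± 0.32, the cytochrome P450 gene CYP81D11 by 3.45 ± 0.28 and the nicotianamine synthase gene NAS2 by 3.96 ± 0.39. The cell wall gene XTH26 rose by 4.15 ± 0.5, the proline-rich protein gene PRP1 by 3.78 ± 0.35 and FRK1, a marker of pattern-triggered immunity, by 2.54 ± 0.47. Root hair genes rose in 7 and fell in 1 of 14 cases (10 higher and 2 lower adjusted over the list alone, median 0.95, camera adjusted p = 0.00499, and adjusted p = 0.629 with an estimated correlation). Endodermis and stele genes, among them the Casparian strip gene CASP1, fell in 4 of 11 cases (5 adjusted over the list alone, median -0.59, camera adjusted p = 0.000184, and adjusted p = 0.113 with an estimated correlation). CASP1 fell by 0.9 ± 0.26. Its call was lost without experiment A, B or E (adjusted p = 0.0611, 0.0504 and 0.192), in experiments C, D and E alone (adjusted p = 0.0956) and without an experiment term (adjusted p = 0.806). Salicylic acid genes rose in 1 of 23 cases in Col-0 (1 adjusted over the list alone) and in 8 in phr1 (11 adjusted over the list alone), and the difference between the genotypes in this response was not tested. In phr1 the list had a median of 0.69 (camera adjusted p = 9.14e-10, and adjusted p = 0.282 with an estimated correlation), with PR2 at 3.38 ± 0.67 and PBS3 at 2.94 ± 0.56. The test called 777 genes in Col-0 (247 higher and 530 lower), 970 in phr1 and 454 in phr1 phl1, and in Col-0 the experiments A to E alone called 166, 133, 6, 17 and 152. Without experiment B the counts were 488 in Col-0 and 605 in phr1, and in phr1 phl1 the count was 145 without C and 151 without D.

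SynCom at low Pi raised the Pi starvation genes of Col-0 against plants without bacteria at low Pi. SPX1 rose by 4.93 ± 0.26, PAP12 by 2.23 ± 0.13 and GDPD3, with 0 counts in 5 of 10 libraries without bacteria, by 5.85 ± 0.36. IPS1 went from 3.01 ± 8.0 to 535 ± 446 CPM (adjusted p = 9.38e-30), and no fold is given because 1 library of experiment B held 25.7 CPM without bacteria, the next 1.93 CPM, and 3 of 10 held 0 counts. Of 23 Pi transport and signalling genes 19 rose and 4 fell (19 higher and 4 lower adjusted over the list alone, median 3.61, camera adjusted p = 4.17e-22). Phosphatase genes rose in 17 of 19 cases (18 adjusted over the list alone, camera adjusted p = 1.37e-26), and membrane lipid genes rose in 14 and fell in 1 of 17 (14 higher and 2 lower adjusted over the list alone, camera adjusted p = 6.93e-21). Salicylic acid genes rose in 18 of 23 cases (19 adjusted over the list alone, median 1.51, camera adjusted p = 4.25e-06, and adjusted p = 0.552 with an estimated correlation), with PR2 at 3.99 ± 0.62 and PBS3 at 3.49 ± 0.49. Pattern-triggered immunity genes rose in 11 of 31 cases (11 adjusted over the list alone, camera adjusted p = 0.0105, and adjusted p = 0.753 with an estimated correlation), with FRK1 at 3.04 ± 0.48. All 14 root hair genes rose (14 adjusted over the list alone, median 1.65, camera adjusted p = 8.13e-05, and adjusted p = 0.403 with an estimated correlation), and photosynthesis genes fell in 20 of 22 cases (20 adjusted over the list alone, median -0.65, camera adjusted p = 7.59e-09, and adjusted p = 0.56 with an estimated correlation). The test called 8334 genes in Col-0, 5141 in phr1 and 2641 in phr1 phl1. Experiments A to E alone called 6162, 2122, 2289, 5153 and 263 in Col-0. Without experiment C the counts were 3370 in phr1 and 761 in phr1 phl1, and without D 638 in phr1 phl1.

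The effect of low Pi differed between plants with and without SynCom in Col-0, by the interaction of Pi and bacteria. The extra low Pi response with SynCom was 4.8 ± 0.36 for SPX1, 2.5 ± 0.24 for the transporter trafficking gene PHF1, 3.48 ± 0.28 for SQD2, 5.39 ± 0.49 for the phospholipase gene NPC4 and 2.11 ± 0.18 for PAP12. The interaction passed upwards for 12 and downwards for 3 of 23 Pi transport and signalling genes (14 higher and 3 lower adjusted over the list alone, median 3.51, camera adjusted p = 1.13e-20). It passed upwards for 13 of 19 phosphatase genes (13 adjusted over the list alone, camera adjusted p = 4.16e-26) and 14 of 17 membrane lipid genes (14 adjusted over the list alone, camera adjusted p = 8.07e-21). Salicylic acid genes passed upwards in 10 of 23 cases (12 adjusted over the list alone, camera adjusted p = 0.0011, and adjusted p = 0.665 with an estimated correlation), with WRKY54 at 1.75 ± 0.44 and PR5 at 2.48 ± 0.74. Photosynthesis genes passed downwards in 13 of 22 cases (17 adjusted over the list alone, camera adjusted p = 1.30e-08, and adjusted p = 0.561 with an estimated correlation), and root hair genes upwards in 5 of 14 (6 adjusted over the list alone, camera adjusted p = 0.0314, and adjusted p = 0.71 with an estimated correlation). In all, 5660 genes passed, 3020 upwards and 2640 downwards, and experiments A to E alone gave 3080, 386, 1007, 2214 and 0 in edgeR. In experiment E alone 1197 genes had an unadjusted p under 0.05, and no other tool was run on single experiments. Without experiment A, 3607 genes passed and PR5 lost its call (adjusted p = 0.0698). In experiments C, D and E alone WRKY54 and PR5 did (adjusted p = 0.0704 and 0.158).

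Both mutants still responded to low Pi with SynCom. In phr1, SPX1 rose by 4.86 ± 0.28, AT4 by 7.88 ± 0.48 and PHT1;2 by 5.98 ± 0.46, and IPS1 was 19.0 ± 16.3 CPM at low and 5.81 ± 0.971 CPM at high Pi. Of 23 Pi transport and signalling genes 17 rose and 3 fell in phr1 (17 higher and 3 lower adjusted over the list alone, median 1.98, camera adjusted p = 7.45e-20). Phosphatase genes rose in 16 of 19 cases (16 adjusted over the list alone, camera adjusted p = 8.07e-21), with PAP17 at 4.68 ± 0.34, and membrane lipid genes in 14 of 17 (14 adjusted over the list alone, camera adjusted p = 4.16e-26), with SQD1 at 2.51 ± 0.16. In phr1 phl1, SPX1 rose by 2.87 ± 0.34, AT4 by 4.53 ± 0.54 and PAP17 by 3.01 ± 0.42. There 11 Pi transport and signalling genes rose (11 adjusted over the list alone, median 1.17, camera adjusted p = 2.77e-07, and adjusted p = 0.0861 with an estimated correlation), with 8 phosphatase genes (8 adjusted over the list alone, camera adjusted p = 3.72e-05, and adjusted p = 0.363 with an estimated correlation) and 9 membrane lipid genes (10 adjusted over the list alone, camera adjusted p = 3.35e-07, and adjusted p = 0.134 with an estimated correlation). Salicylic acid genes rose in 13 cases in phr1 (13 adjusted over the list alone, camera adjusted p = 2.41e-06, and adjusted p = 0.537 with an estimated correlation) and in 15 in phr1 phl1 (19 adjusted over the list alone, camera adjusted p = 4.28e-08, and adjusted p = 0.393 with an estimated correlation). Photosynthesis genes fell in 10 cases in phr1 (12 adjusted over the list alone, camera adjusted p = 0.000189, and adjusted p = 0.728 with an estimated correlation) and 8 in phr1 phl1 (11 adjusted over the list alone, camera adjusted p = 0.00137, and adjusted p = 0.768 with an estimated correlation). The test called 4629 genes in phr1, where experiments A to E alone gave 1401, 687, 4337, 1109 and 103, and 3682 in phr1 phl1, where C, D and E alone gave 3075, 1930 and 2. Without experiment C the counts were 2738 in phr1 and 897 in phr1 phl1, and without D 759 in phr1 phl1.

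**Figure D3:**
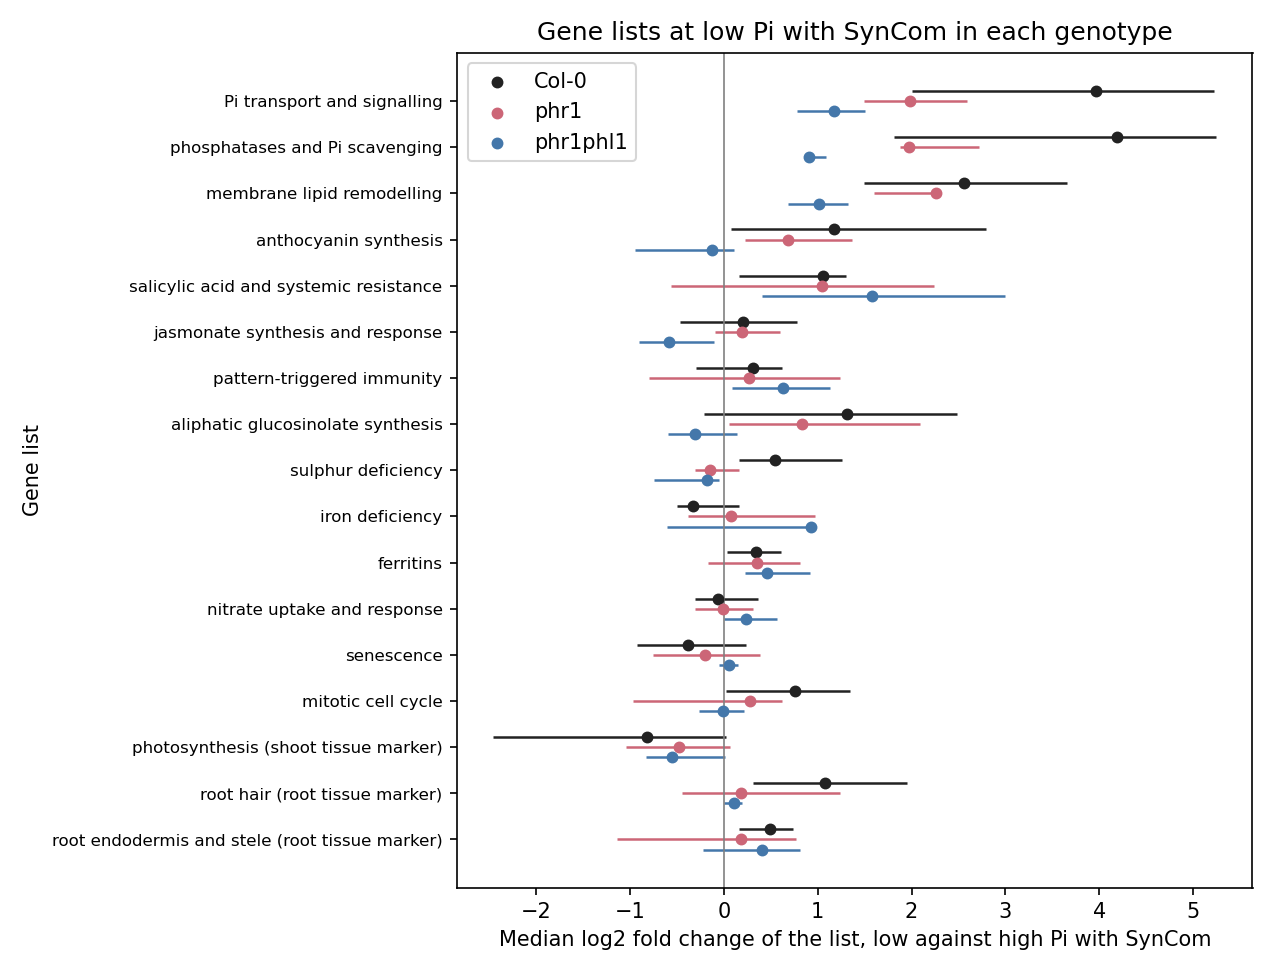
Median log2 fold change of each gene list at low against high Pi with SynCom (points) in Col-0, phr1 and phr1 phl1, with lines from the lowest to the highest median of single experiments. The phosphatase list had medians of 4.19 in Col-0, 1.97 in phr1 and 0.91 in phr1 phl1.

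At low Pi with SynCom, phr1 held less mRNA of many Pi starvation genes than Col-0. IPS1 fell by 4.6 ± 0.36, SPX3 by 4.46 ± 0.36, PHT1;9 by 2.03 ± 0.22, PAP22 by 2.56 ± 0.26, PAP24 by 3.85 ± 0.31, NPC4 by 3.55 ± 0.29 and GDPD3 by 3.0 ± 0.27 relative to Col-0. Of 23 Pi transport and signalling genes 16 were lower and 1 higher (2 higher and 17 lower adjusted over the list alone, median -1.21, camera adjusted p = 7.26e-10). Phosphatase genes were lower in 15 of 19 cases (17 adjusted over the list alone, camera adjusted p = 1.08e-18) and membrane lipid genes in 9 of 17 (9 adjusted over the list alone, camera adjusted p = 2.70e-05, and adjusted p = 0.273 with an estimated correlation). Salicylic acid genes were higher in 10 of 23 cases (10 adjusted over the list alone, median 0.45, camera adjusted p = 0.00143, and adjusted p = 0.683 with an estimated correlation), with PR1 at 2.44 ± 0.63, FMO1 at 1.99 ± 0.37 and ALD1 at 2.48 ± 0.42. Sulphur deficiency genes were lower in 9 of 11 cases (9 adjusted over the list alone, camera adjusted p = 3.92e-06). Iron deficiency genes were higher in 8 and lower in 1 of 21 cases (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0878). Root hair genes were lower in 13 of 14 cases (13 adjusted over the list alone, median -0.97, camera adjusted p = 5.87e-05, and adjusted p = 0.393 with an estimated correlation), and CASP1 fell by 0.95 ± 0.26. The test called 4971 genes, and experiments A to E alone gave 3272, 1586, 1299, 2575 and 6. Of the genes called, 45.4% had the same sign in experiment E alone, against 93.6% to 98.1% in the others. A fit of the compared groups alone called 1292, and leaving out A, B or D gave 3006, 2746 or 2889. PR1 and CASP1 lost their calls in that fit (adjusted p = 0.0848 and 0.0688). PR1 lost it also without C (adjusted p = 0.217) and CASP1 without B or without an experiment term (adjusted p = 0.103 and 0.133).

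The double mutant also held less mRNA of many Pi starvation genes than Col-0 at low Pi with SynCom. PHT1;2 fell by 5.39 ± 0.44, SPX3 by 6.13 ± 0.61, PEPC1 by 5.58 ± 0.53, PAP22 by 4.07 ± 0.45, NPC4 by 5.65 ± 0.47 and GDPD3 by 4.76 ± 0.51, while PHO2 rose by 2.62 ± 0.17. Of 23 Pi transport and signalling genes 17 were lower and 2 higher (2 higher and 18 lower adjusted over the list alone, median -2.09, camera adjusted p = 7.55e-11). Phosphatase genes were lower in 17 of 19 cases (17 adjusted over the list alone, camera adjusted p = 4.79e-18) and membrane lipid genes in 12 of 17 (12 adjusted over the list alone, camera adjusted p = 1.27e-07, and adjusted p = 0.113 with an estimated correlation). Iron deficiency genes were higher in 17 and lower in 1 of 21 cases (17 higher and 1 lower adjusted over the list alone, median 2.07, camera adjusted p = 4.90e-05, and adjusted p = 0.219 with an estimated correlation), with the transcription factor genes BHLH038 at 3.22 ± 0.45 and BHLH100 at 4.17 ± 0.6 and the peptide gene IMA3 at 4.04 ± 0.55. Aliphatic glucosinolate genes were lower in 15 of 19 cases (16 adjusted over the list alone, camera adjusted p = 0.000645, and adjusted p = 0.65 with an estimated correlation), sulphur deficiency genes in 8 of 11 (9 adjusted over the list alone, camera adjusted p = 1.30e-05, and adjusted p = 0.0563 with an estimated correlation) and root hair genes in 12 of 14 (13 adjusted over the list alone, median -1.81, camera adjusted p = 2.75e-07, and adjusted p = 0.19 with an estimated correlation). Salicylic acid genes were higher in 9 of 23 cases (10 adjusted over the list alone, camera adjusted p = 0.0314, and adjusted p = 0.797 with an estimated correlation), with PR1 at 3.15 ± 0.77. The test called 6895 genes, experiments C, D and E alone gave 2990, 5188 and 62 (the same sign for 69.9% of the genes called in E), and a fit of the compared groups alone called 1820. Without C the count was 4500 and without D 3800, where PR1 lost its call (adjusted p = 0.597). BHLH038 was not called in limma-voom (adjusted p = 0.102).

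The low Pi response with SynCom differed between Col-0 and both mutants by the interaction of genotype and Pi. IPS1 passed downwards in phr1 and in phr1 phl1 (adjusted p = 1.66e-17 and 3.67e-13), with 0 counts in 5 of 10 Col-0 libraries at high Pi, so no size is given. In phr1 the response of PHT1;9, which held 0 counts in 4 of those 10, fell relative to Col-0 by 2.84 ± 0.52, NPC4 by 3.31 ± 0.56 and the organic cation transporter gene OCT1 by 4.08 ± 0.68. In phr1 phl1 the response fell by 2.87 ± 0.42 for SPX1, 1.44 ± 0.21 for PAP12, 4.66 ± 0.8 for PAP22 and 2.36 ± 0.33 for SQD2. Pi transport and signalling genes passed downwards in 5 and upwards in 1 of 23 cases in phr1 (1 higher and 8 lower adjusted over the list alone, camera adjusted p = 3.06e-09), and in 11 and 2 in phr1 phl1 (2 higher and 11 lower adjusted over the list alone, camera adjusted p = 2.70e-12). Phosphatase genes passed downwards in 3 of 19 cases in phr1 (10 adjusted over the list alone, camera adjusted p = 1.89e-15) and 11 in phr1 phl1 (12 adjusted over the list alone, camera adjusted p = 4.61e-19). Glucosinolate genes passed downwards in 14 of 19 cases in phr1 phl1 (17 adjusted over the list alone, camera adjusted p = 1.42e-07, and adjusted p = 0.427 with an estimated correlation). The interaction passed for 575 genes in phr1, where experiments A to E alone gave 590, 1, 24, 12 and 1 (the same sign for 52.5% in E), and for 3121 genes in phr1 phl1, where C, D and E alone gave 560, 1140 and 0 (the same sign for 68.9% in E), with 744 genes at an unadjusted p under 0.05 in E. The count for phr1 was unstable: it ran over 46 to 3065 when each experiment was left out, was 2 in experiments C, D and E, 11 in a fit of the compared groups alone and 294 without 4 libraries that stood apart, chosen after seeing the data. In experiments C, D and E alone PHT1;9, NPC4 and OCT1 lost their calls in phr1 (adjusted p = 0.595, 0.39 and 0.459). PHT1;9 lost it also without B (adjusted p = 0.0505). The count for phr1 phl1 was 1924, 937 or 1271 without A, C or D, and 852 in experiments C, D and E alone. The fit of all groups set Col-0 from A to E against phr1 phl1 from C, D and E. Experiment E, where the low Pi response of Col-0 was smaller, thus weighed more in phr1 phl1 than in Col-0. That can enlarge this interaction. Without bacteria edgeR called 0 genes for phr1 and 0 for phr1 phl1, with 281 and 489 at an unadjusted p under 0.05. DESeq2 called 0 and 0 and limma-voom 0 and 0. Both edgeR numbers are a share under 0.05 of the 18926 genes tested, fewer than p-values spread evenly would give. The edgeR test may thus be too cautious there, and 0 calls do not show equal responses.

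In the other conditions edgeR called few genes between the mutants and Col-0. At high Pi with SynCom, IPS1 was higher than in Col-0, at 5.81 ± 0.971 CPM in phr1 and 6.56 ± 1.91 CPM in phr1 phl1 against 0.272 ± 0.364 CPM (adjusted p = 7.37e-05 and 0.000284), while at low Pi with SynCom it was lower. The phosphatase gene PAP10 fell by 1.23 ± 0.2 in phr1 at high Pi without bacteria, where its adjusted p was 0.486 in experiments C, D and E alone, and by 1.61 ± 0.2 at low Pi without bacteria. In phr1 phl1, PHO2 rose by 0.99 ± 0.17 and FLC, a repressor of flowering, by 2.68 ± 0.33 at high Pi without bacteria. The iron deficiency peptide genes IMA1 and IMA2, near-identical and so uncertain one from the other, rose by 3.53 ± 0.66 and 3.44 ± 0.64 in phr1 phl1 at high Pi with SynCom, where iron deficiency genes rose in 2 of 21 cases (6 adjusted over the list alone, camera adjusted p = 3.38e-06, and adjusted p = 0.134 with an estimated correlation). AT3G01345 stood at 153 ± 35.6 CPM in Col-0, 0.981 ± 1.95 CPM in phr1 and 0.198 ± 0.333 CPM in phr1 phl1 at high Pi without bacteria. The test called 15 genes in phr1 at high Pi without bacteria, 23 at high Pi with SynCom and 11 at low Pi without bacteria. The corresponding counts for phr1 phl1 were 19, 24 and 12. Most of these counts were unstable: with 1 experiment left out they ran over 9 to 16, 13 to 19 and 9 to 15 in phr1 and over 10 to 69, 7 to 35 and 8 to 15 in phr1 phl1. At high Pi the count for phr1 was 9 without bacteria when experiment A was left out, and with SynCom 15 without A, 13 without B, 14 without D and 15 without E. For phr1 phl1 it was 10 without C, 10 without D and 69 without E in the absence of bacteria, and 7 without C and 35 without E with SynCom. With no experiment term, phr1 at high Pi gave 24 genes without bacteria and 15 with SynCom, and phr1 phl1 gave 77 without bacteria. In experiments C, D and E alone the 3 counts were 7, 9 and 8 in phr1 and 10, 10 and 11 in phr1 phl1. Fits of the compared groups alone gave 10, 42 and 12 in phr1 and 10, 21 and 24 in phr1 phl1. At high Pi without bacteria 3 of 40 splits of the phr1 phl1 and Col-0 libraries, the real one included, called as many genes, the highest other 691. Without experiment C, IMA1, IMA2 and IPS1 lost their calls in phr1 phl1 at high Pi with SynCom (adjusted p = 0.445, 0.377 and 0.0561). IMA1 and IMA2 were not called there in DESeq2 (adjusted p = 0.116 and 0.12), in limma-voom (adjusted p = 0.0844 and 0.0844) or in experiments C, D and E alone (adjusted p = 0.0727 and 0.0914). In DESeq2, 27 genes were higher and 8 lower in phr1 at high Pi without bacteria, against 5 and 10 in edgeR. For phr1 phl1 in that condition DESeq2 called 137 genes, against 19 in edgeR, where 2621 had an unadjusted p under 0.05.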

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

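The tests of fewer counts, of swapped labels and of a batch difference in experiment E were chosen after the result was seen. Among 48 groups of values tested for a library far from the others 5 held one. Chance gives about 1 in 20 such groups only for independent, normally distributed values. CPM values near 0 and libraries paired by experiment need not follow that, so the 5 are not read as an excess. IPS1 stood at 0.561 CPM in replicate 2 of experiment A in Col-0 at high Pi without bacteria, where the next library had 0.128 CPM. At low Pi without bacteria in Col-0, replicate 1 of experiment B had 25.7 CPM of IPS1 and the next library 1.93 CPM. PHL1 reached 972 CPM in replicate 1 of experiment D in phr1 phl1 at high Pi without bacteria, against 193 CPM in the next library. PHR1 was 27.2 CPM in replicate 1 of experiment E in phr1 phl1 at low Pi without bacteria, against 41.5 CPM in the next lowest library. Replicate 1 of experiment A in phr1 at low Pi without bacteria held 8514673 counts, against 5670149 in the next library.

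The effect of low Pi differed between groups in 3 interaction tests. The Pi by SynCom interaction in Col-0 passed for 5660 genes, the phr1 by Pi interaction with SynCom for 575 and the phr1 phl1 by Pi interaction with SynCom for 3121. The splits of these interactions shuffled only the bacteria labels (Pi by SynCom) or the genotype labels, within each Pi level. They ask whether those labels matter at all, and so cannot decide on the interaction alone. In a fit of the compared groups the first interaction called 5458 genes and the highest of the other splits 109 (1 of 40 splits, the real one included). For phr1 the real split called 11 genes, against 575 in the fit of all groups, and the highest other 0 (1 of 40). Experiments A to E alone gave 590, 1, 24, 12 and 1 genes for this interaction. For phr1 phl1 the real split called 1425 and the highest other 2716, with a median of 0 among the others (2 of 40). That highest split exchanged labels in experiments D and E and none in C. Fitted alone, experiments C, D and E called 560, 1140 and 0 genes in edgeR, with 744 at an unadjusted p under 0.05 in E.

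The low Pi response with SynCom in Col-0 was smaller in experiment E, where 43 genes were called. Fewer counts in experiment E are argued against, because its Col-0 libraries at low Pi with SynCom had a median of 6447193 counts and those of the other experiments 4215045. At high Pi with SynCom its median of 2828960 counts was lower than in the others, but experiment D called 5721 genes with medians of 1863591 at low and 3847852 at high Pi. Swapped Pi labels within experiment E are argued against by the median of the Pi transport and signalling list, which was 2.0 there and above 0. A batch difference between experiments stays open: the median of experiment E lay within the range of the others in 1 of 3 genotypes. The design gives no biological explanation for it, and none was tested.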

How the results depend on the processing

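The fit without 4 libraries was chosen after seeing the data, and the other alternatives before. All 146 named gene and contrast pairs had passed in the main fit, and 131 of them came from the rule for named genes. That choice, and refits of the same libraries, favour agreement. Of the 146 pairs 122 passed with the same sign in each of the 16 alternatives that could be fitted for them. The other 24 missed the threshold in at least 1. Among those, low Pi without bacteria in Col-0 turned the fold of HSP17.6II to 0.28 in experiments C, D and E, and leaving out each experiment gave -3.28 (without C) to 0.55 (without A). RLE and upper-quartile scaling changed no named call. The estimated correlation left 30 of 183 list calls. The cause of the shifts below was not tested. Fits of fewer libraries hold fewer samples, which alone would tend to lower counts, yet some rose. SynCom at high Pi in Col-0 gave 777 genes in the fit of all groups and 1232 in the compared groups alone. The fit of all groups shares 1 estimate of spread per gene, while the median residual SD differed between groups. In Col-0 at low Pi it was 0.443 with SynCom and 0.286 without bacteria. The block of experiment and number (replicate block) moved 1 count by over 1.5 times, that of low Pi in Col-0 without bacteria to 3 genes.

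Without an experiment term (no replicate block), low against high Pi called 8 genes in Col-0 and 19 in phr1 without bacteria, and 6303, 2050 and 1175 in Col-0, phr1 and phr1 phl1 with SynCom. In that fit SynCom called 256, 358 and 81 genes at high Pi and 5039, 2357 and 768 at low Pi in the same order. The mutant contrasts gave 24, 15 and 1790 for phr1 at high Pi without bacteria, at high Pi with SynCom and at low Pi with SynCom. For phr1 phl1 they gave 77 at high Pi without bacteria and 4049 at low Pi with SynCom. The interactions gave 2659 for Pi by SynCom, 72 for phr1 by Pi and 923 for phr1 phl1 by Pi with SynCom.

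In experiments C, D and E alone, low Pi called 0 genes in Col-0 (edgeR, 274 at an unadjusted p under 0.05, no other tool run) and 1 in phr1 without bacteria, and 5273 in Col-0 with SynCom. SynCom called 295 genes in Col-0 and 485 in phr1 at high Pi, and 4280 and 3415 at low Pi. The contrast of phr1 with Col-0 gave 7 at high Pi without bacteria and 9 and 1070 at high and low Pi with SynCom, and phr1 phl1 gave 10 and 10 at high Pi without bacteria and with SynCom. The interactions gave 1865 for Pi by SynCom, 1 for phr1 by Pi without bacteria, 2 with SynCom and 852 for phr1 phl1 with SynCom.

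A fit of the compared groups alone gave 1 and 1 genes at low Pi without bacteria in Col-0 and phr1, and 2941 and 2407 with SynCom in phr1 and phr1 phl1. SynCom at high Pi gave 1232 in Col-0 and 291 in phr1 phl1. The mutant contrasts gave 42 and 1292 for phr1 with SynCom at high and low Pi, and 10, 24 and 1820 for phr1 phl1 without bacteria at high and low Pi and with SynCom at low Pi. The genotype by Pi interactions with SynCom gave 11 and 1425.

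DESeq2 called 3, 76 and 4 genes at low Pi without bacteria, 35 for phr1 and 137 for phr1 phl1 at high Pi without bacteria. It gave 14 higher and 19 lower in phr1 phl1 at high Pi with SynCom, against 13 and 11 in edgeR, and 12 and 6 at low Pi without bacteria, against 6 and 6. Limma-voom called 1 and the stricter filter 2 genes at low Pi without bacteria in Col-0. In phr1 without bacteria upper-quartile scaling called 2 (both higher) and no filter 1. No filter gave 367 and the fit without 4 libraries 294 genes for the phr1 by Pi interaction with SynCom.

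Leaving out each experiment in turn moved the counts for low Pi without bacteria over 2 to 9 in Col-0 and 0 to 1 in phr1. With SynCom they ran over 2738 to 5053 in phr1 and 759 to 5250 in phr1 phl1. SynCom at high Pi gave 488 to 674, 605 to 1039 and 145 to 412 in Col-0, phr1 and phr1 phl1, and at low Pi 3370 to 5174 and 638 to 3583 in phr1 and phr1 phl1. The Pi by SynCom interaction gave 3607 to 6611. The mutant contrasts gave 9 to 16 for phr1 at high Pi without bacteria and 13 to 19 and 2746 to 7083 at high and low Pi with SynCom. For phr1 phl1 they gave 10 to 69 and 7 to 35 at high Pi without bacteria and with SynCom, and 3800 to 7844 at low Pi with SynCom. The genotype by Pi interactions gave 0 to 1 for phr1 without bacteria, 46 to 3065 with SynCom and 937 to 4616 for phr1 phl1 with SynCom. Total counts as low as 955174 limit what can be said of weakly expressed genes.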

Other observations

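The tests of linkage to PHR1 and PHL1, of a larger share of root tissue and of a scaling error were chosen after the result was seen. A set of genes differed from Col-0 in all 4 conditions, beside the mutated ones, and was chosen after its values were seen. In phr1, ESM1, a myrosinase-associated protein gene, was higher by 0.83 to 1.46, QQS by 1.88 to 2.4 and AT5G35760 by 3.9 to 4.99 on the log2 scale over the conditions, and PAP10 fell by 1.23 to 1.61. In phr1 phl1, FLC was higher by 2.31 to 2.68, PHO2 by 0.99 to 2.62 and ARP9 by 0.64 to 0.93. There were 7 such genes in phr1 and 5 in phr1 phl1, and 2 of them in both, a count that shared Col-0 libraries can raise. Not every call was stable: at low Pi ESM1 missed the threshold without experiment C, D or E, with SynCom (adjusted p = 0.0655, 0.0577 and 0.144) and without bacteria (adjusted p = 0.414, 0.0605 and 0.132). At high Pi with SynCom, PHO2 missed it without D or E (adjusted p = 0.0508 and 0.071), FLC in a fit of the compared groups alone (adjusted p = 0.0795) and PAP10 in experiments C, D and E (adjusted p = 0.113).

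A region linked to PHR1 is argued against as the source of these genes, because 0% of the 10 genes of either genotype lie on the chromosome of PHR1. A region linked to PHL1 stays open for phr1 phl1, where 40% of the 5 genes lie on the chromosome of PHL1. A background variant of the mutant lines is consistent with 8.33% of the pairs of gene and genotype passing the genotype by Pi interaction with SynCom. The genes had been chosen for differing in all conditions, which favours that outcome, and PHO2 was the one that passed (adjusted p = 1.38e-06). A lasting effect of the mutations themselves was not tested.

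At low Pi with SynCom in Col-0, photosynthesis genes were lower and root hair genes higher. A larger share of root tissue as the whole source would raise the root hair list and the endodermis and stele list alike. The mean of the root hair list was higher by 0.765, with a standard error of 0.249. That error is over genes taken as independent, not over libraries or experiments, so it cannot decide the question. A scaling error shared by all genes of a library would move both lists alike. The mean of the root hair list exceeded that of the photosynthesis list by 1.84, with a standard error of 0.157 over genes. The pattern had been chosen for that difference, so the value restates it and decides nothing. A change in the share of root tissue or of root hairs stays open, as does a change within the tissues.

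Other splits of the compared libraries, 40 per comparison, were counted within experiments. Where only the real split reached its count (1 of 40), this argues against a chance assignment of single libraries and nothing more. That was so for low Pi with SynCom in Col-0 (real 7406, highest other 0), phr1 (2941 and 7) and phr1 phl1 (2407 and 2280). The high value for phr1 phl1 came from a split that exchanged all labels of experiments C and D and those of 1 pair in E, so it nearly mirrors the real one. Only the real split reached its count also for SynCom at high Pi (1232 and 209 in Col-0, 862 and 0 in phr1, 291 and 0 in phr1 phl1). At low Pi the same held (6743 and 3027, 3983 and 1243, 2312 and 1008), where the highest others kept or exchanged all labels of most experiments.

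For phr1 against Col-0 only the real split reached its count at high Pi without bacteria (10 and 0) and with SynCom (42 and 3). The same held at low Pi without bacteria (12 and 3) and with SynCom (1292 and 140). For phr1 phl1 this was so at high Pi with SynCom (21 and 1) and at low Pi without bacteria (24 and 1). A chance assignment could not be excluded for phr1 phl1 at high Pi without bacteria, where 3 of 40 splits called as many genes (real 10, highest other 691). The highest split exchanged all labels of experiments C and D and part of those in E, so it nearly mirrors the real one. Its count, many times the real one, points to a structure of the samples that was not tested. At low Pi with SynCom 2 of 40 splits called as many genes (real 1820, highest other 2124, median of the others 0). The highest kept all labels of experiments C and D, which alone called 2990 and 5188 genes, and exchanged labels only in E, which alone called 62, so it is close to the real split. Without bacteria chance could not be excluded for low Pi in Col-0 (4 of 40, real 1, highest other 45) and in phr1 (2 of 40, 1 and 1). The real split called 0 genes in edgeR for low Pi in phr1 phl1 without bacteria (highest other 0) and for the genotype by Pi interactions without bacteria (highest other 1 for each mutant). There 40 of 40 splits necessarily gave as many, so the count of splits decides nothing. In the fit of all groups these contrasts gave 1099, 281 and 489 genes at an unadjusted p under 0.05. For the interactions that is a share under 0.05 of the 18926 genes tested, fewer than p-values spread evenly would give.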
